A study of Homo sapiens with 15 samples.

How the data were processed

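RNA was measured in 15 libraries of HepG2, a human liver cancer cell line grown in DMEM with fetal bovine serum. The libraries were poly(A) selected and sequenced as read pairs on a DNBSEQ-T7. They form 5 groups of 3 libraries, which the series text calls biological replicates: control cells, cells given palmitate (a saturated fatty acid, used in the series to model insulin resistance), and cells given palmitate with sodium butyrate at 0.5, 1 or 1.5 mM (low, medium and high). Butyrate is a short-chain fatty acid and an inhibitor of histone deacetylases. The labels give palmitate as 200 mM, and whether that unit was meant is not known. All libraries were taken at 48 h. The library names give 48 h of palmitate for the palmitate group but 24 h of palmitate and 24 h of butyrate for the butyrate groups, so time with palmitate alone also differs between them. No group received butyrate without palmitate.

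The deposited table holds raw counts per Ensembl gene, 15 columns, with no normalization. Beside them the deposited table holds FPKM values, made by the authors from the same counts: divided by a gene length and by the library total, they were matched within 1% for all 11013 genes with at least 100 counts in every library. The submitters' notes name FastQC, HISAT2, featureCounts and DESeq2 and the builds GRCh38 and hg38, without versions. The annotation release and the strand setting of the counting are not stated. Both reads of a pair appear to have been counted, since 69.19% of the counts from 1 to 20 were even, against 50.48% of those from 100 to 1000. Of 39133 genes in the table, 37848 had an entry in GENCODE 29, which gave positions, and 10813 had no symbol. Totals ran from 35349827 to 61086976 counts per library. Depth limits genes near 0: a count of 0 allows about 3 read pairs in a library, for counting error only, and no fold against a group of 0 counts is given.

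Genes were kept by the filterByExpr rule of edgeR with the 5 groups, which left 20309 genes. Counts were scaled by TMM and all 15 libraries were fitted in 1 quasi-likelihood model with a coefficient per group (edgeR 4.0.16 in R 4.3.3). Unless another tool is named, adjusted p is the Benjamini-Hochberg value of the edgeR quasi-likelihood test over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 change was derived from that test. Levels are in CPM, the count over the scaled library total in the unit edgeR gives, as mean ± SD of 3 libraries. The dose trend is the least-squares slope, in log2 per mM, over the 4 groups with palmitate. A common biological coefficient of variation of 8.88% was estimated.

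Gene lists, 30 in number, were fixed before the data were examined, as were the comparisons, the thresholds and the rule for named genes. Another 9 lists were added afterwards and are described only among the other observations. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation. Of 842 names on the fixed lists, 14 had no row in the table. The rule named the 6 largest rises and the 6 largest falls among called genes with an average log2 CPM of at least 2, a standard symbol and no overlap between the libraries of both groups, then up to 4 called members with the smallest adjusted p per list, then a fixed panel of 24 genes. For the trend it named 5 slopes in each direction. Some of the genes so named are not reported here.

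Alternatives were DESeq2 (1.42.0), its size factors in edgeR, library totals alone, no filter on low counts, at least 1 CPM in 3 libraries, only the groups compared, the replicate number as a block, limma-trend on the FPKM values with a pseudocount of 1 or 0.1, an adjusted p under 0.01, a 2-fold change, and leaving out each library in turn. Further alternatives were chosen after seeing the data. The pipeline was tested on simulated counts with 200 changed genes per comparison, and overlaps of contrasts that share libraries were set against 20 simulated draws. Labels were also shuffled, over 10 splits of 6 libraries or 100 drawn regroupings. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3).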

Results

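Gene counts were measured in 15 HepG2 libraries in 5 groups of 3: control, palmitate, and palmitate with low, medium or high butyrate. Total counts were 46457472, 46664120 and 51080106 in the control libraries, 52060396, 45627010 and 61086976 in palmitate, 44557148, 35349827 and 59980853 in low, 39344307, 50162494 and 43687829 in medium and 43917285, 47320903 and 46436616 in high butyrate. Control and palmitate libraries lay together on the first principal component (67.1% of the variance), low and medium butyrate lay together further along it, and high butyrate lay farthest. Transcripts of the mitochondrial genome took 5.97% ± 0.154 of the counts in control, 6.68% ± 0.617 in palmitate, 6.81% ± 0.689 in low, 6.60% ± 0.513 in medium and 8.48% ± 1.04 in high butyrate (SD, n = 3). Histone genes took 0.0791% ± 0.00151 in control and 0.126% ± 0.00497 in high butyrate. Between pairs of libraries of a group, the chi-square per gene ran from 7.11 to 11.2 in control and from 28.2 to 93.2 in palmitate, so the palmitate libraries were the least alike. All p-values measure only the spread between these libraries.

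**Figure D1:**
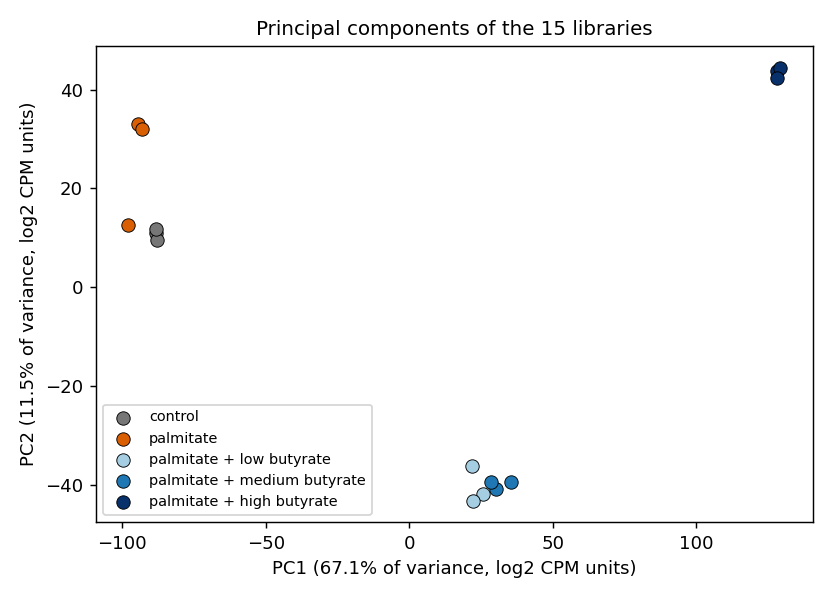
The first 2 principal components of log2 CPM (axes in log2 CPM units, with the share of variance), 1 point per library and 1 colour per group. Low and medium butyrate form 1 cloud, high butyrate stands apart, and palmitate library 1 lies nearest the 3 controls.

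Palmitate against control addressed what the fatty acid exposure alone does to these cells. Few genes were called, 22 in all, 4 of them at 2-fold or more. TGM2 (ENSG00000198959, chromosome 20, 38127387 to 38166578, hg38), which encodes a protein-crosslinking transglutaminase, fell 1.52-fold, from 78.4 ± 2.80 to 51.5 ± 4.44 CPM (SD, n = 3; log2 change -0.61, SE 0.0637, adjusted p = 0.000108). MYEOV, a gene first described in myeloma, fell 1.51-fold to 11.8 ± 0.864 CPM (adjusted p = 0.00132), and RAB3B, a small GTPase of vesicle secretion, fell 1.47-fold to 28.0 ± 3.57 CPM (adjusted p = 0.00578). MT1G (ENSG00000125144, chromosome 16, 56666731 to 56668065), a zinc-binding metallothionein, rose 1.87-fold, from 14.8 ± 2.11 to 27.7 ± 3.01 CPM (log2 change 0.90, SE 0.125, adjusted p = 0.00226). ODC1, the first enzyme of polyamine synthesis, rose 1.29-fold to 634 ± 64.8 CPM (adjusted p = 0.0411).

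The other named calls of this comparison had an adjusted p from 0.0188 to 0.0497. TNNC2, a troponin of fast muscle, rose 3.05-fold to 1.89 ± 0.778 CPM (adjusted p = 0.0188), SURF2 rose 1.45-fold and PFDN2, a subunit of the prefoldin chaperone, rose 1.25-fold. PALM3, KIAA0513, the large scaffold protein gene AHNAK and KRT19, a keratin of bile duct cells, fell 1.64-fold, 1.52-fold, 1.47-fold and 1.26-fold. In all, 7 genes were higher and 15 lower at an adjusted p under 0.05, with 2894 genes at an unadjusted p under 0.05. Each of the 22 separated the 3 libraries of one group from the 3 of the other, as did 16.1% of all genes tested, where chance gives 10%. With library totals alone as the scaling, 40 genes were called and the share higher went from 31.8% to 12.5%. It was over 50% with DESeq2 (65.4%), with no filter on low counts (58.3%), with voom quality weights (55.2%) and without palmitate library 2 (67.1%), and 9.59% without palmitate library 1, so the balance of rises and falls has no settled direction. DESeq2 called 376 genes, 19 of the 22 among them, and only 3 of the 22 were called when the 6 libraries were fitted alone.

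The count rested on single libraries: it was 7, 4 and 8 without control library 1, 2 and 3, and 219, 1175 and 7 without palmitate library 1, 2 and 3. TGM2 kept its call in each of these fits, and MYEOV and MT1G did as well. The call of RAB3B was lost without control library 2 (adjusted p = 0.0541), and that of TNNC2 without control library 1 (0.124), control library 2 (0.135) or palmitate library 3 (0.125). KRT19 and ODC1 lost theirs without any single control (KRT19 0.114, 0.218 and 0.167, ODC1 0.199, 0.172 and 0.114) or palmitate library 3 (0.131 and 0.122). The same libraries ended the calls of SURF2 (0.260, 0.119, 0.179 and 0.142), PFDN2 (0.260, 0.205, 0.135 and 0.131), PALM3 (0.199, 0.216, 0.0948 and 0.125), KIAA0513 (0.161, 0.113, 0.167 and 0.125) and AHNAK (0.219, 0.119, 0.0789 and 0.125). With the 6 libraries alone MYEOV was lost (0.208), as were RAB3B, TNNC2, KRT19, ODC1, SURF2, PFDN2, PALM3, KIAA0513 and AHNAK (each 0.397). On FPKM with a pseudocount of 1, MT1G (0.0886), RAB3B (0.0589), TNNC2 (0.115), KRT19 (0.0551), ODC1 (0.0988), SURF2 (0.0589), PFDN2 (0.0988), PALM3 (0.113), KIAA0513 (0.222) and AHNAK (0.125) were lost.

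**Figure D2:**
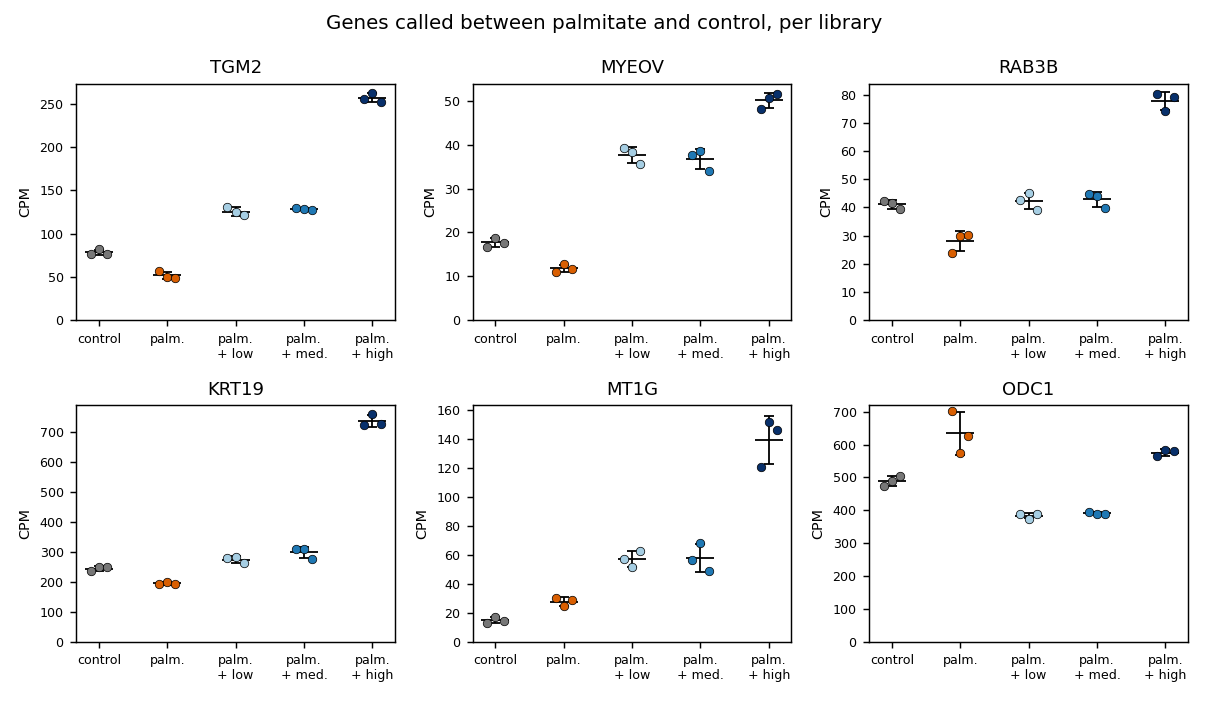
CPM (linear axes from 0) of 6 genes called between palmitate and control, 1 point per library, with the mean (line) and SD (bars) of 3 libraries in each group. TGM2, MYEOV, RAB3B and KRT19 lie lower with palmitate alone than in control, and MT1G and ODC1 lie higher.

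Genes of insulin action and lipid handling were not called with palmitate. The insulin receptor INSR stood at 57.4 ± 8.72 CPM against 68.1 ± 4.18 in control (adjusted p = 0.217), and IRS1, the adaptor below the receptor, at 127 ± 18.6 against 136 ± 4.36 (adjusted p = 0.594). PLIN2, which coats lipid droplets (adjusted p = 0.487), CPT1A, which admits fatty acids to mitochondria (0.352), the stress gene TRIB3 (0.514), the fatty acid synthase gene FASN (0.619) and ALB, encoding albumin (0.404), were not called either. Without palmitate library 2, INSR (log2 change -0.38, adjusted p = 0.0120) and ALB (log2 change 0.29, adjusted p = 0.0386) passed.

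As a group, genes of the ATF4 and amino acid response shifted upward with palmitate by camera (adjusted p = 2.9e-06, median log2 change 0.14), and this call held with an estimated correlation (adjusted p = 0.0176). No member of its 29 was called over all genes and 7 were higher adjusted over the list alone, MTHFD2 of folate metabolism having the smallest adjusted p over all genes (0.0913). Cell cycle genes (2 of 50 higher adjusted over the list alone) also shifted upward (camera adjusted p = 7.1e-06, adjusted p = 0.283 with an estimated correlation). Metallothioneins had 1 member called and 4 of 10 higher adjusted over the list alone (camera adjusted p = 0.0385, adjusted p = 0.443 with an estimated correlation), and camera lost that call without control library 1 (0.0584), control library 3 (0.115) or palmitate library 2 (0.212).

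Smaller shifts without a called member were upward for nuclear oxidative phosphorylation (camera adjusted p = 0.00420, adjusted p = 0.573 with an estimated correlation) and for transcripts of the mitochondrial genome (0.00781, adjusted p = 0.561 with an estimated correlation), and both ended without palmitate library 1 (0.622 and 0.136). Insulin signalling genes shifted downward by a median log2 of -0.09 (camera adjusted p = 0.00420, adjusted p = 0.283 with an estimated correlation; 0.0523 without palmitate library 1), with 0 of 42 members called by edgeR, over all genes or adjusted over the list alone. Hepatocyte products (up, camera adjusted p = 0.0278, adjusted p = 0.346 with an estimated correlation), cholesterol synthesis (down, 0.0278, adjusted p = 0.283 with an estimated correlation), and stromal and skin or intestinal genes (both down, 0.0385, adjusted p = 0.283 with an estimated correlation) also passed camera, with 0 members called. Each of these 4 lists lost its camera call without palmitate library 2 (0.0747, 0.0859, 0.180 and 0.111). Other single libraries ended them too: control 3 (0.115) and palmitate 1 (0.0523) for hepatocyte products, control 1 (0.0827) and palmitate 3 (0.0600) for cholesterol synthesis, control 2 (0.0599), control 3 (0.102) and palmitate 3 (0.135) for stromal genes, and control 3 (0.115) for skin or intestinal genes. On FPKM the calls of hepatocyte (0.0793), stromal (0.360) and skin or intestinal genes (0.375) ended. With fry, oxidative phosphorylation (0.355), mitochondrial transcripts (0.278), insulin signalling (0.0726), hepatocyte products (0.0915), cholesterol synthesis (0.0726), stromal genes (0.0726) and metallothioneins (0.139) did not pass. The remaining 20 fixed lists did not pass. The cholangiocyte list held 1 called member, KRT19. With palmitate the median log2 change of genes also went with level, from -0.07 under an average log2 CPM of 0 to 0.03 over 5. Camera did not match for level, so list shifts with palmitate may in part follow it, which was not tested. A smooth trend with transcript length and GC content had its largest SD, 0.232 log2, in palmitate library 1. No list was tested with that trend removed.

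Low butyrate against palmitate compared cells given 0.5 mM butyrate with cells given palmitate alone. By the library names this set 24 h of palmitate and 24 h of butyrate against 48 h of palmitate. Here and for the other doses against palmitate, shorter palmitate exposure was not separated from butyrate, and changes named for a dose are differences between these groups. Genes that were almost silent in palmitate came on: EEF1A2 (chromosome 20, 63488012 to 63499322), an elongation factor normally of muscle and nerve, rose 63.1-fold, from 1.07 ± 0.455 to 67.3 ± 3.50 CPM (log2 change 5.98, SE 0.142, adjusted p = 1.65e-17). CRABP2, which carries retinoic acid, rose 42.6-fold to 20.8 ± 1.16 CPM. SYNGR1, of synaptic vesicles (44.9-fold), ADGRB2, an adhesion receptor (44.5-fold), SLC17A8, a glutamate transporter (37.4-fold), and FBLN2, of the extracellular matrix (36.5-fold), rose from under 0.2 CPM. Falls were smaller: ATF5, a stress transcription factor, fell 3.44-fold from 20.2 ± 3.24 to 5.83 ± 0.884 CPM (adjusted p = 1.69e-09), and PUS10, FAM110C, FAM174A, GTF3C6 and PCYT1B fell between 2.82-fold and 3.30-fold.

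Genes of cell division fell: of 50 tested, 37 were lower and 3 higher with low butyrate (camera adjusted p = 2.3e-08, adjusted p = 0.114 with an estimated correlation), among them CCNA2, a cyclin of S phase, 2.24-fold to 75.3 ± 1.49 CPM, and TYMS, which makes thymidylate, 2.47-fold. Of 25 genes known to respond to histone deacetylase inhibitors, 17 rose and 3 fell (camera adjusted p = 8.5e-05; 0.0275 with an estimated correlation), such as CDKN1A, the cell cycle inhibitor p21, 1.77-fold to 104 ± 4.98 CPM, and CDH1, E-cadherin, 3.16-fold. Fatty acid and triglyceride synthesis genes rose in 16 of 25 and fell in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 0.00519, adjusted p = 0.195 with an estimated correlation). FASN rose 2.76-fold from 1760 ± 475 to 4852 ± 205 CPM (adjusted p = 4.46e-09), and SREBF1, its transcriptional activator, rose 1.90-fold. Lipid droplet and lipoprotein genes rose in 14 of 22 and fell in 2 (camera adjusted p = 0.00806, adjusted p = 0.161 with an estimated correlation), with PLIN4, a droplet coat protein, 2.76-fold higher. Metallothioneins rose in 8 of 10 (camera adjusted p = 0.00125, adjusted p = 0.166 with an estimated correlation), MT1A 8.44-fold and MT1G 2.06-fold. In this paragraph and the next, counts adjusted over the list alone were the same unless given.

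Further lists that passed camera with low butyrate were apoptosis regulators (3 up, 14 down; adjusted p = 0.0123, adjusted p = 0.166 with an estimated correlation), the list of cell cycle kinase inhibitors and p53 targets (3 up, 13 down; 0.0331, adjusted p = 0.319 with an estimated correlation) and the ATF4 response (2 up, 12 down; 0.0343, adjusted p = 0.166 with an estimated correlation; 0.0516 without palmitate library 1). TRIB3, an inhibitor of AKT induced by ATF4, fell 1.62-fold. Genes of butyrate transport and use rose in 8 of 18 and fell in 2 (0.0343, adjusted p = 0.169 with an estimated correlation), among them ACSM1, an acyl-CoA synthetase of the mitochondrion, 4.65-fold, and that camera call ended without palmitate library 2 (0.0862), palmitate library 3 (0.0538) or low library 1 (0.0544). Nuclear oxidative phosphorylation genes fell in 12 of 37 and rose in 1 (0.0305, adjusted p = 0.627 with an estimated correlation; 0.203 without palmitate library 1 and 0.0508 without low library 2). Genes typical of other cell types rose as well: 10 of 13 stromal, endothelial and immune genes (0.00125, adjusted p = 0.114 with an estimated correlation), 9 of 17 neuronal genes (0.00806, adjusted p = 0.114 with an estimated correlation) and 5 of 9 skin or intestinal genes, with 1 lower (0.0229, adjusted p = 0.114 with an estimated correlation). At 1 CPM in 3 libraries the calls of the ATF4, kinase inhibitor and p53 target, and oxidative phosphorylation lists (each 0.133), apoptosis (0.0632) and butyrate transport (0.108) ended. On FPKM those of ATF4 and oxidative phosphorylation (0.0777), kinase inhibitors and p53 targets (0.0654) and skin or intestinal genes (0.0578) ended. Insulin signalling genes (7 up, 12 down of 42) did not pass as a group (camera adjusted p = 0.319). IGFBP1, a secreted binder of insulin-like growth factor, fell 1.53-fold (adjusted p = 0.0137, but 0.0519 with DESeq2, 0.0787 on FPKM, 0.0732 without palmitate library 1 and 0.0921 without low library 3), and IRS1 rose 1.17-fold (adjusted p = 0.0210, but 0.0968 with the 6 libraries alone, 0.0989 with length and GC trends removed, 0.128 without palmitate library 1 and 0.0624 without low library 2). In total 5261 genes rose and 4871 fell, 2964 and 278 of them at least 2-fold. Direction went with level: of genes with an average log2 CPM under 0, 1749 rose and 157 fell. Of those over 5, 1039 rose and 2430 fell. Camera set each list against all genes without matching for level. Shifts of lists, such as those of other cell types, may in part follow level, which was not tested. At 53.6% of genes the libraries of both groups did not overlap, where chance gives 10%.

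Medium butyrate against palmitate, at 1 mM, gave nearly the same picture. EEF1A2 rose 64.2-fold to 68.4 ± 1.05 CPM, ADGRB2 58.1-fold, SYNGR1 45.9-fold, CRABP2 44.6-fold, SLC17A8 40.7-fold and COL1A1, a fibrillar collagen, 44.6-fold to 3.04 ± 0.302 CPM. ATF5 fell 3.66-fold, the phosphatidylcholine synthesis gene PCYT1B 3.48-fold, PUS10 3.32-fold, the death receptor gene FAS 3.08-fold and FAM174A 2.95-fold. SERF1B was also among the called falls, but it has a near-identical copy, SERF1A, its palmitate libraries differed widely (12 ± 14.2 CPM), and the call ended without palmitate library 3 (adjusted p = 0.128), so it stays uncertain. In total 5505 genes rose and 4963 fell, and 53.7% of genes did not overlap. Direction again went with level (1829 up and 172 down under an average log2 CPM of 0, 1096 up and 2493 down over 5).

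The same lists passed camera with medium as with low butyrate except nuclear oxidative phosphorylation (3 up, 11 down; adjusted p = 0.0800; 1 and 9 adjusted over the list alone). Cell cycle genes fell in 38 of 50 and rose in 2 (4.0e-10, adjusted p = 0.115 with an estimated correlation), and histone deacetylase inhibitor genes rose in 17 of 25 and fell in 1 (2.0e-05; 0.0175 with an estimated correlation). Stromal genes rose in 11 of 13 (12 adjusted over the list alone; 0.00101, adjusted p = 0.115 with an estimated correlation), lipid droplet genes in 13 of 22 with 2 lower (14 and 2 adjusted over the list alone; 0.00273, adjusted p = 0.122 with an estimated correlation) and fatty acid synthesis genes in 18 of 25 with 1 lower (0.00421, adjusted p = 0.179 with an estimated correlation). Metallothioneins rose in 8 of 10 (0.00234, adjusted p = 0.176 with an estimated correlation), neuronal genes in 9 of 17 (0.0128, adjusted p = 0.127 with an estimated correlation), skin or intestinal genes in 6 of 9 with 1 lower (0.0261, adjusted p = 0.122 with an estimated correlation). Apoptosis regulators (3 up, 15 down; 0.0128, adjusted p = 0.168 with an estimated correlation) and the ATF4 response (2 up, 12 down; 0.0261, adjusted p = 0.152 with an estimated correlation) shifted downward. So did the list of kinase inhibitors and p53 targets (3 up, 13 down; 0.0483, adjusted p = 0.369 with an estimated correlation), a call lost without palmitate library 2 (0.0572), medium library 1 (0.0545) or medium library 2 (0.0674). Butyrate transport genes (8 up, 2 down; 0.0372, adjusted p = 0.176 with an estimated correlation) lost theirs without palmitate library 2 (0.0855), palmitate library 3 (0.0502) or medium library 1 (0.0549). At 1 CPM in 3 libraries the ATF4 (0.121), kinase inhibitor and p53 target (0.174), apoptosis (0.0623) and butyrate transport lists (0.1) did not pass. On FPKM the ATF4 (0.0613), kinase inhibitor and p53 target (0.0731) and skin or intestinal lists (0.0715) did not pass.

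Medium against low butyrate asked whether the doses differ. No gene was told apart: CDKN1A stood at 111 ± 3.49 CPM with medium and 104 ± 4.98 with low butyrate, FASN at 5073 ± 125 and 4852 ± 205, and TXNIP at 170 ± 12 and 147 ± 13.6. edgeR called 0 genes, with 490 at an unadjusted p under 0.05. DESeq2 called 0 as well, with 400 at an unadjusted p under 0.05. The cell cycle list shifted downward with the higher dose by camera (adjusted p = 1.9e-06, median log2 change -0.07, adjusted p = 0.497 with an estimated correlation), with 0 members called by edgeR over all genes or adjusted over the list alone. That camera call ended without medium library 2 (0.0738) and with fry (0.465). At 8.15% of genes the 3 libraries of each group did not overlap, where chance gives 10%. In simulated data with a 1.5-fold change between these groups, 52.2% of the changed genes were called, and 83.8% of those with an average log2 CPM of at least 2.

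High butyrate against palmitate, at 1.5 mM, gave the largest response. ATP1B2, a sodium pump subunit of nerve and glia, rose 295-fold, from 0.0901 ± 0.0780 to 27.9 ± 4.36 CPM (SD, n = 3; log2 change 8.20, SE 0.275, adjusted p = 1.97e-16). FBLN2 rose 284-fold to 39.9 ± 2.08 CPM, PHOSPHO1, a phosphatase of bone mineralization, 275-fold to 26.0 ± 0.411 CPM, COL1A1 246-fold, ADGRB2 226-fold, and DES, the muscle filament desmin, 173-fold to 14.1 ± 0.162 CPM. The non-coding RNA LINC00261 (ENSG00000259974, chromosome 20, 22547671 to 22578642), next to the liver factor gene FOXA2, fell 25.5-fold, from 199 ± 15.1 to 7.81 ± 0.347 CPM (log2 change -4.67, SE 0.0829, adjusted p = 3.99e-20). FOXA2 itself fell 2.71-fold. SLC26A9, an anion transporter (19.8-fold), LINC00513 (19.1-fold), LGI1 (18.8-fold), LINC01146 (17.2-fold) and AP1M2, a sorting adaptor of epithelia (16.5-fold), also fell.

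High butyrate lowered cell cycle genes throughout: 48 of 50 fell and 1, TK1, rose (camera adjusted p = 1.8e-19, median log2 change -1.82, adjusted p = 0.0240 with an estimated correlation). CCNA2 fell 8.98-fold to 18.8 ± 0.301 CPM (adjusted p = 2.28e-19), TYMS 8.91-fold, CDC25A, a phosphatase that activates cyclin-dependent kinases, 6.44-fold, and CDC45, of the replication helicase, 5.90-fold. Genes known to respond to histone deacetylase inhibitors rose in 21 of 25 and fell in 2 (camera adjusted p = 2.0e-06, median log2 change 2.29, adjusted p = 0.00912 with an estimated correlation). CDKN1A rose 4.97-fold to 292 ± 8.71 CPM (adjusted p = 9.00e-18), TXNIP, an inhibitor of thioredoxin and glucose uptake, 11.7-fold to 1164 ± 70.4 CPM, the histone gene H2BC12 7.50-fold and the synaptotagmin SYT11 67.9-fold. Metallothioneins rose in 9 of 10 (camera adjusted p = 0.00101, adjusted p = 0.177 with an estimated correlation), MT1A 25.8-fold, MT1X 11.2-fold and MT2A 4.89-fold. In this comparison counts adjusted over the list alone were the same unless given.

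Liver products fell with high butyrate: of 34 hepatocyte genes, 24 were lower and 5 higher (camera adjusted p = 0.000481, median log2 change -0.80, adjusted p = 0.139 with an estimated correlation). ASGR1, a receptor for desialylated glycoproteins, fell 4.50-fold, the bile acid receptor NR1H4 4.02-fold, AFP 2.39-fold and ALB 2.16-fold, from 6308 ± 1190 to 2915 ± 76.5 CPM, while HNF4A, a master factor of hepatocytes, fell 1.16-fold, a call lost with library totals (0.304), at 1 CPM in 3 libraries (0.0680) and on FPKM (0.332). Acute phase genes (3 up, 10 down of 16) stood at a camera adjusted p of 0.0519, CP, ceruloplasmin, falling 9.07-fold. Bile acid and drug metabolism genes went both ways (9 up, 10 down; camera adjusted p = 0.684), NR0B2, a repressor of bile acid synthesis, falling 6.47-fold and CYP1A1, a monooxygenase of xenobiotics, rising 21.8-fold.

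Among lipid genes, cholesterol synthesis and uptake genes fell in 18 of 25 and rose in 2 (camera adjusted p = 0.00184, median log2 change -0.86, adjusted p = 0.139 with an estimated correlation), ACAT2, of sterol and acyl metabolism, 9.36-fold and HMGCS1, of early sterol synthesis, 2.68-fold. Fatty acid and triglyceride synthesis genes rose in 17 of 25 and fell in 6, and did not pass as a group (camera adjusted p = 0.272). FASN stood 2.94-fold and SREBF1 3.81-fold higher than with palmitate, and ELOVL6, an elongase, 2.48-fold lower. In the lipid droplet list (9 up, 6 down; 0.272) PLIN5, which ties droplets to mitochondria, rose 55.4-fold and PLIN4 8.21-fold, while PLIN2 was not called (1003 ± 4.29 against 988 ± 81.6 CPM; adjusted p = 0.873). Fatty acid oxidation genes went both ways (12 up, 15 down; 0.801; median log2 change -0.05, mean 0.27). PDK4, which limits glucose oxidation, rose 21.5-fold to 2.05 ± 0.333 CPM and the PPAR partner CREB3L3 11.7-fold, while CPT1A was not called (adjusted p = 0.997).

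Genes of insulin action and glucose handling moved in both directions with high butyrate. Of 42 insulin signalling genes, 15 rose and 13 fell (15 and 12 adjusted over the list alone; camera adjusted p = 0.853). AKT1, a kinase of the pathway, fell 2.26-fold, IRS1 1.43-fold to 88.3 ± 4.15 CPM and INSR 1.27-fold, the last lost with library totals (0.0661) and on FPKM (0.133). INPPL1, a lipid phosphatase that limits insulin signals, fell 2.73-fold and PTPN1, a phosphatase of the insulin receptor, rose 1.82-fold. IGFBP1 fell 8.81-fold, from 527 ± 120 to 59.9 ± 7.31 CPM (adjusted p = 2.26e-11). Gluconeogenesis genes (8 up, 8 down; 9 and 8 adjusted over the list alone; 0.853) included PCK1, 7.52-fold higher, and glycolysis genes (8 up, 14 down; 0.355; median log2 change -0.32, mean 0.18) included HK1, a hexokinase, 11.5-fold higher.

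Stress lists fell as groups with high butyrate. The ATF4 response fell in 17 of 29 and rose in 5 (camera adjusted p = 0.0145, adjusted p = 0.139 with an estimated correlation), TRIB3 5.74-fold, the cystine transporter SLC7A11 4.30-fold and the glycine transporter SLC6A9 3.96-fold, while SESN2, an inhibitor of mTORC1 signals, rose 2.00-fold. ER stress genes fell in 18 of 24 and rose in 6 (camera adjusted p = 0.0427, adjusted p = 0.355 with an estimated correlation), MANF, a secreted ER stress protein, 3.01-fold, though the sensor ERN1 rose 2.60-fold. That list lost its call at 1 CPM in 3 libraries (0.157) and on FPKM (0.0523). Autophagy and lysosome genes rose in 18 of 29 and fell in 6 (0.0400, adjusted p = 0.223 with an estimated correlation), such as the cholesterol exporter of lysosomes NPC1, 2.64-fold, and the protease CTSB, 2.23-fold. Not passing were apoptosis regulators (8 up, 14 down; 0.0809), with BIK 16.9-fold higher and BID 8.08-fold lower, and the list of kinase inhibitors and p53 targets (8 up, 16 down; 0.227), with FAS 10.1-fold lower. Inflammation genes (6 up, 8 down; 7 and 8 adjusted over the list alone; 0.636), NRF2 targets (15 up, 15 down; 0.691), interferon genes (16 up, 8 down; 0.491), nuclear oxidative phosphorylation (5 up, 21 down; 0.0519), histone deacetylases and sirtuins (11 up, 5 down; 0.227), and butyrate transport genes (8 up, 6 down; 0.761) did not pass either. The adaptor MYD88 fell 7.34-fold and IFI6, an interferon-induced gene, rose 20.6-fold.

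Of the lists of other cell types only the neuronal one passed with high butyrate in the main fit. Neuronal genes rose in 12 of 17 and fell in 3 (camera adjusted p = 0.0400, median log2 change 1.96, adjusted p = 0.177 with an estimated correlation), SYP, of synaptic vesicles, 18.7-fold and CHGB, of secretory granules, 13.7-fold. Stromal, endothelial and immune genes (9 up, 1 down of 13; 0.0519) and skin or intestinal genes (7 up, 1 down of 9; 0.0582) did not pass. Both lay near the threshold. Over all fixed lists 9 passed in the main fit, 10 to 13 with 1 library left out and 12 with the replicate number as a block. On FPKM 8 passed, and 2 with an estimated correlation. Not passing here therefore does not show that these lists stopped shifting at the high dose. LYZ, lysozyme, fell 2.33-fold. Epithelial and mesenchymal genes (14 up, 10 down; 0.684) included CDH1, 4.07-fold higher, and SNAI1, a repressor of CDH1, 9.79-fold higher. Cholangiocyte genes (4 up, 5 down of 12; 0.853) included KRT19, 3.78-fold higher. Transcripts of the mitochondrial genome were higher in 4 of 13 (3 adjusted over the list alone; 0.463).

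In total 7663 genes rose and 6869 fell with high butyrate, 4869 and 2732 of them at least 2-fold, and 72.1% of genes did not overlap, where chance gives 10%. Direction again went with level: 2834 genes rose and 559 fell under an average log2 CPM of 0, and 1505 rose and 3093 fell over 5. Camera did not match for level, so list shifts with high butyrate may in part follow it. With library totals as the scaling, the median of all genes moved by 0.14 on the log2 scale (0.11 on FPKM, 0.04 with DESeq2 size factors), so changes are relative to the TMM median and smaller ones have no certain sign.

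**Figure D3:**
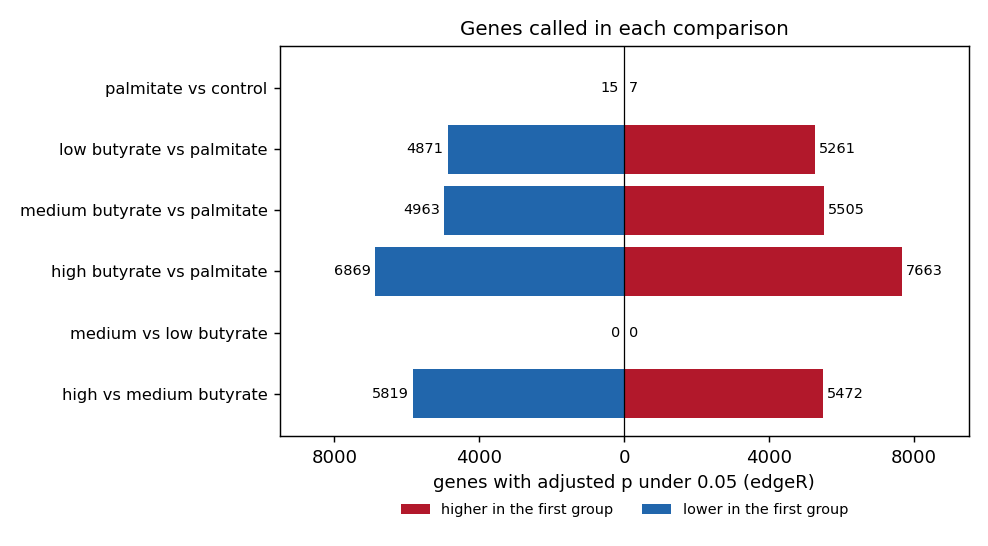
Genes called higher (right) and lower (left) in the first group of each comparison at an adjusted p under 0.05 (edgeR), as bars from 0 with their counts. Palmitate against control had 22 and medium against low butyrate 0.

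High against low and against medium butyrate tested the differences between doses. TXNIP was 7.92-fold, CDKN1A 2.80-fold and SREBF1 2.01-fold higher with high than with low butyrate, and IGFBP1 5.76-fold, TRIB3 3.55-fold, ALB 2.37-fold and IRS1 1.68-fold lower. FASN did not differ past the threshold (5170 ± 165 against 4852 ± 205 CPM; adjusted p = 0.545). Against low butyrate 5859 genes were higher and 5850 lower, and against medium 5472 and 5819. Cell cycle genes were lower in 48 of 50 against both (48 and 49 adjusted over the list alone; camera adjusted p = 3.5e-24 and 2.3e-24, adjusted p = 0.0112 and 0.0109 with an estimated correlation). Histone deacetylase inhibitor genes were higher in 21 of 25 against both, with 2 lower (22 and 21 higher adjusted over the list alone; 3.0e-07 and 3.6e-07, adjusted p = 0.00559 and 0.00587 with an estimated correlation).

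The trend over 0, 0.5, 1 and 1.5 mM fitted a straight line to the dose: 7535 genes had a positive and 6761 a negative slope. Such a slope weighs the palmitate and high-butyrate groups most, and its 14296 calls stood beside 14532 for high butyrate against palmitate. Medium against low butyrate had 0 called genes, so a called slope does not show a step at each dose. The steepest rises were ATP1B2 (4.94 log2 per mM, SE 0.170, adjusted p = 3.31e-16), PHOSPHO1 (4.92), FBLN2 (4.91), COL1A1 (4.83) and ADGRB2 (4.77), and the steepest falls were LINC00261 (-2.82 log2 per mM, SE 0.0512, adjusted p = 6.32e-20), SLC26A9 (-2.60), LINC00513 (-2.56) and LGI1 (-2.55). SERF1B (-2.76) is uncertain, having a near-identical copy. Cell cycle genes had a negative slope in 48 of 50 and a positive one in 1 (camera adjusted p = 1.0e-19, adjusted p = 0.0229 with an estimated correlation).

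**Figure D4:**
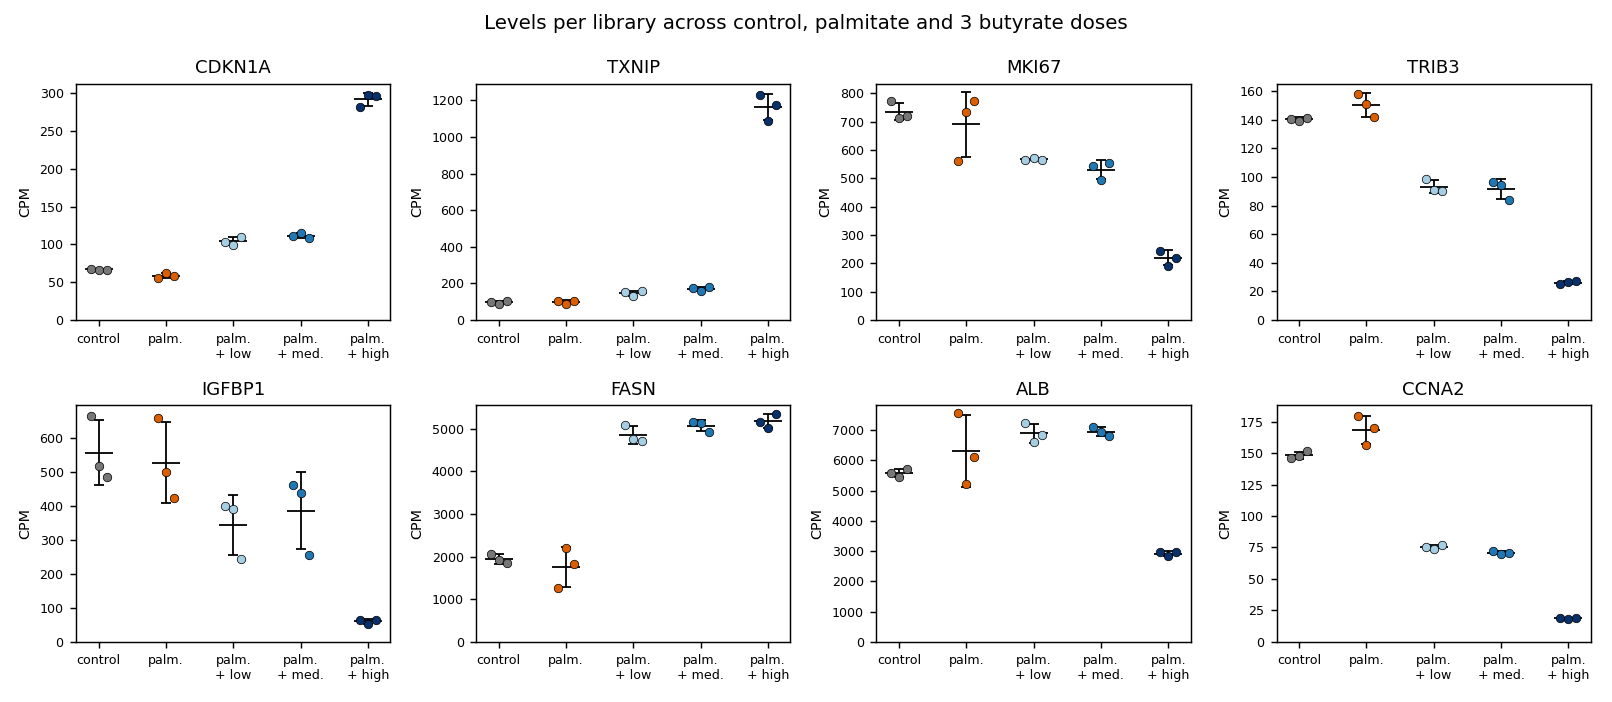
CPM (linear axes from 0) of 8 genes in the 5 groups, 1 point per library, with the mean (line) and SD (bars) of 3 libraries. CDKN1A and TXNIP are highest and MKI67, TRIB3, IGFBP1, ALB and CCNA2 lowest with high butyrate, while FASN is at a like level with all 3 doses.

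Against untreated control, cells given palmitate and butyrate differed at 9019 (low), 9518 (medium) and 14217 genes (high). CDKN1A stood at 66.8 ± 0.294 CPM in control, FASN at 1947 ± 111, TXNIP at 96.8 ± 8.98, ALB at 5578 ± 135 and IGFBP1 at 557 ± 95.8. Histone deacetylase inhibitor genes were higher in 15, 16 and 21 of 25 with low, medium and high butyrate and lower in 1, 1 and 3, the same counts adjusted over the list alone (camera adjusted p = 7.0e-05, 1.4e-05 and 2.0e-06; adjusted p = 0.0258, 0.0158 and 0.00908 with an estimated correlation). Insulin signalling genes were higher in 5 and lower in 15 of 42 with low butyrate (5 and 16 adjusted over the list alone; camera adjusted p = 0.0253, adjusted p = 0.337 with an estimated correlation).

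The doses acted on overlapping sets of genes: 10631 were called in the same direction against palmitate by at least 2 doses, 8040 of them by all 3 (4173 up, 3867 down), while 500 were called in opposite directions by different doses. Independent lists would share 8123 and 941, and simulated data in which nothing changed, with almost no calls, shared at most 1. CDKN1A, TXNIP, PLIN4 and MT1A rose, and CCNA2, TYMS and TRIB3 fell, with each dose. Across genes, which are not independent replicates, the changes with low and medium butyrate had r = 0.959 and a covariance of 1.49, against 0.484 and 0.0347 in simulated data from shared palmitate libraries alone. Low against control and high against palmitate, which share no library, had r = 0.771 and a covariance of 1.70.

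Some genes called with palmitate went the opposite way in the butyrate groups. By their names these had 24 h of palmitate and 24 h of butyrate against 48 h of palmitate, and whether palmitate stayed on is not stated, so an effect of shorter exposure to palmitate was not separated from that of butyrate. TGM2 rose with high butyrate to 257 ± 5.22 CPM, above control, as did MYEOV (50.2 ± 1.72), RAB3B (77.8 ± 3.22), PALM3 (12.3 ± 0.769) and KIAA0513 (26.1 ± 0.305), and the same 5 rose with low butyrate. PFDN2 and SURF2 fell with high butyrate, to 47.9 ± 1.12 and 8.33 ± 0.826 CPM, and MT1G, raised by palmitate, rose further to 139 ± 16.7 CPM. Of the 22 genes called with palmitate, 14, 15 and 13 went the opposite way with low, medium and high butyrate and 3, 3 and 7 the same way, where independent lists give 5.57, 5.78 and 8.03 opposite. Simulated data in which butyrate did nothing gave at most 1, but they hold almost no butyrate calls and so do not set what sharing libraries alone adds to these counts. The covariance with the palmitate change was -0.26, -0.27 and -0.27, against -0.035 in simulated data with no effect. The correlation was -0.35, -0.34 and -0.23, where sharing the palmitate libraries alone gave a median of -0.29, -0.30 and -0.30 with butyrate doing nothing and near -0.50 with no effect at all. The draws with butyrate doing nothing called a median of 1162 genes between palmitate and control (1042 to 1329), against 22 in the data. All draws gave every group the same spread, while the real palmitate libraries were the least alike. These simulated values are therefore no firm baseline. Both contrasts use the 3 palmitate libraries, which cannot be split into 2 groups of 2, so part of the excess may come from sharing them.

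These counts of opposed genes rested on single libraries. Low butyrate opposed 5, 2 and 4 genes without control library 1, 2 and 3, 188, 917 and 4 without palmitate library 1, 2 and 3, and 4 without any one low library. Medium butyrate opposed 4, 2 and 4, then 189, 905 and 4, and 4, 4 and 8 without medium library 1, 2 and 3. High butyrate opposed 6, 3 and 4, then 132, 890 and 5, and 6, 4 and 4 without high library 1, 2 and 3. With library totals alone the opposed genes numbered 27, 28 and 26, and the share of them raised by palmitate fell by over 10 points, from 14.3%, 20% and 30.8% to 3.70%, 3.57% and 7.69%. That share was 65.0%, 65.2% and 69.4% with DESeq2, 56.5%, 58.2% and 66.2% with no filter, 56.4%, 55.7% and 60.9% with voom quality weights and 70.5%, 70.5% and 71.2% without palmitate library 2, which turns the balance the other way. Without palmitate library 1 it was 3.72%, 3.70% and 6.82%.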

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

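The genes called between palmitate and control and those opposed by butyrate changed much with the processing. Between palmitate and control (22), DESeq2 called 376, library totals alone 40, no filter on low counts 600, only the groups compared 3, limma on FPKM 9 (pseudocount 1) and 7 (0.1), an adjusted p under 0.01 left 6 and a 2-fold change 4. Without single libraries the count ran from 4 to 1175. Of the alternatives chosen after seeing the data, voom with library quality weights called 2191. It weighted palmitate library 1, 2 and 3 by 0.276, 0.504 and 2.75. Removing length and GC trends and halving the counts, also chosen then, moved no count of this comparison by over 1.5 times. For genes opposed by low, medium and high butyrate, DESeq2 gave 246, 244 and 271, library totals 27, 28 and 26, no filter 434, 440 and 400, only the groups compared 1, 1 and 2, FPKM 6, 7 and 4 (pseudocount 1) and 5, 6 and 4 (0.1), voom weights 1538, 1553 and 1475, an adjusted p under 0.01 4, 4 and 4, a 2-fold change 1, 1 and 3, and leaving out libraries 2 to 917, 2 to 905 and 3 to 890. Between medium and low butyrate, 39 genes were called with no filter, 1 with only the groups compared, and 1 on FPKM with either pseudocount. The cause was not tested.

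A 2-fold change left 3242, 3430 and 7601 genes for low, medium and high butyrate against palmitate, 4194 and 3769 for high against low and medium, 2829, 3046 and 7228 against control, 4526 for the trend and 3520 shared by the doses. Leaving out libraries gave 9031 to 10152, 9373 to 10498 and 13983 to 14609 against palmitate, 10723 to 10999 (high against low), 10293 to 10579 (high against medium), 0 (medium against low), 7859 to 8171, 8339 to 9049 and 13637 to 13834 against control, 13761 to 14531 for the trend and 9694 to 10701 shared. With the replicate number as a replicate block, palmitate against control had 15 genes, within 1.5 times, and high butyrate opposed 7, the only count of calls to move by more. The block also ended the call of the list of kinase inhibitors and p53 targets with medium butyrate (0.0511), those of SURF2, PFDN2, PALM3, KIAA0513 and AHNAK with palmitate (each 0.0521) and that of DDIT3 with high butyrate (0.0551). Whether the numbers pair the libraries was not settled: of 30 pairs, 9 correlated over 0.1 and 13 under 0 (-0.326 to 0.334), and 8 of 15 libraries were closest to their own number. No test of pairing was run. The rotation test fry turned fatty acid oxidation and cholangiocyte genes upward with high butyrate (adjusted p = 0.00201 and 0.000216), against control (0.000800 and 0.00263) and over dose (0.00193 and 0.000215), and fatty acid synthesis downward between high and low (0.0247) or medium butyrate (0.0151). Of 321 counts under alternatives 237 stayed within 1.5 times. Of 9385 values of named genes 9179 kept direction and call, 150 lost and 55 gained a call and 1 reversed (to 0.00391 log2, adjusted p = 0.953, with length and GC trends removed), and of 4129 list results 3741 kept, 173 lost, 207 gained and 8 reversed.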

Other observations

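The tests of the 9 added gene lists, of genes silent in palmitate, of myosin counts in palmitate library 2, of simulated genes with an average log2 CPM of at least 2, and all 3 tests of the myosin cluster were chosen only after the results were seen. With high butyrate, genes of DNA repair, ribosome assembly and the proteasome, on lists added then, shifted downward by camera. Camera did not match for level, and of all 5575 genes with an average log2 CPM over 5, 3093 fell and 1505 rose. Shifts of these lists may in part follow level, which was not tested. All 24 DNA repair genes fell (camera adjusted p = 5.1e-10, median log2 change -1.10; adjusted p = 0.0370 with an estimated correlation), FANCI, of crosslink repair, from 81.7 to 18.0 CPM, the exonuclease EXO1 from 37.4 to 5.41 and the checkpoint kinase CHEK1 from 55.1 to 8.70. Ribosome biogenesis genes fell in 26 of 30 (7.4e-08; adjusted p = 0.0965 with an estimated correlation), UTP20, of the small subunit processome, from 120 to 27.4 CPM, and proteasome genes fell in 19 of 30 and rose in 2 (0.000208; adjusted p = 0.206 with an estimated correlation). Coagulation and complement genes fell in 18 of 28 and rose in 5 (0.0106; adjusted p = 0.206 with an estimated correlation), PROC, which encodes protein C, from 156 to 42.0 CPM. Counts of replication histone genes rose in 10 of 18 and fell in 1 (camera adjusted p = 0.0356, adjusted p = 0.206 with an estimated correlation), H3C10 from 2.04 to 14.5 CPM. The libraries were poly(A) selected, so RNA of these genes without a poly(A) tail was not measured. Not passing were cancer-testis genes (6 up, 1 down; 0.0656), with PRAME, silent in most adult tissues, at 29.8 against 1.46 CPM, ribosomal proteins (3 up, 14 down; 3 and 13 adjusted over the list alone; 0.0559), haemoglobin genes (2 up; 0.565) and lipid transporters of the ABC family (8 up, 6 down; 0.565). Other counts adjusted over the list alone were the same. With palmitate alone, ribosome biogenesis genes shifted upward (camera adjusted p = 2.4e-08; adjusted p = 0.15 with an estimated correlation), with 0 called over all genes and 16 of 30 higher adjusted over the list alone. Proteasome (3.8e-05; adjusted p = 0.259 with an estimated correlation), ribosomal protein (0.000798; adjusted p = 0.555 with an estimated correlation) and DNA repair genes (0.0259; adjusted p = 0.332 with an estimated correlation) also shifted upward, with 0 called over all genes and 0, 2 and 0 higher adjusted over the list alone.

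Genes silent in palmitate came on with high butyrate. Of 14679 genes with at most 3 counts in each palmitate library, 110 reached 1 CPM in all 3 high-butyrate libraries, 91 of them protein coding, against 5 with low butyrate, 9 with medium and 0 in control. DPYSL5, of growing axons, reached 10.8 ± 0.615 CPM, ALPG, a placental-type phosphatase, 10.2 ± 0.461, TNFRSF1B, a TNF receptor, 8.75 ± 1.03, and STAC2 7.15 ± 0.670.

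Few genes were called between palmitate and control, 22 in all, and 31 with length and GC trends removed, which argues against such trends hiding a large response. By chi-square per gene, palmitate library 2 differed from the controls by 11.4 to 15.9 and from palmitate library 1 by 93.2, though on the second principal component library 1 (12.7), not 2 (33.0), lay near the controls (9.66 to 11.8). In the planned test it lay on the palmitate side in 72.7%, 67.7% and 50.6% of genes called between the other palmitate libraries and controls with control 1, 2 and 3 left out, and the lowest, 50.58, came out as predicted for an untreated library. Its 230 counts of 5 myosin genes, against 0, 0 and 2 in the controls, a test chosen afterwards, argue against an untreated library, but not against a weaker exposure. The count also rested on single palmitate libraries: it was 219, 1175 and 7 without library 1, 2 and 3, and 2191 with voom quality weights. Those weights were 0.276, 0.504 and 2.75 for palmitate library 1, 2 and 3, so the 2191 calls rested mostly on library 3. The 22 calls therefore do not show that the response was small, and the larger counts do not show that it was large. A weak response to palmitate is a possible biological explanation, and it was not tested.

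Low and medium butyrate were not told apart, while high butyrate differed from both. Of genes simulated with a 1.5-fold change, 52.2% were called, so too few libraries may hide differences. At an average log2 CPM of at least 2 the share was 83.8%, which argues against this for changes of at least 1.5-fold in such genes. Smaller changes were not simulated, so too few libraries may hide them at any level. The slope of medium minus low on high minus palmitate over 12260 genes was 0.0312, and the largest of the other 9 splits was 0.0299, so the same exposure in both groups stays open. A response in proportion to the dose would give a slope near 1/3, and 0.0312 argues against it. The slope on high minus palmitate was 0.417 for low minus control and 0.448 for medium minus control, contrasts that also differ in palmitate. Part of the high-butyrate response was thus already present with low butyrate. This argues against a response that only steepens between 1 and 1.5 mM. A response present at the low dose, nearly flat to the medium dose and larger again at the high dose is a possible biological explanation, and it was not tested.

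Fast myosin genes of a cluster on chromosome 17 were counted in all palmitate libraries and hardly in controls. MYH4 (ENSG00000264424, 10443290 to 10469559), a myosin of fast muscle, had 0, 0 and 0 counts in control, 68, 152 and 242 in palmitate, 87, 174 and 329 in low, 216, 81 and 255 in medium and 25, 22 and 17 in high butyrate. Muscle markers elsewhere moved by a median of -0.414% of the MYH4 rise, which argues against muscle RNA, though 1 of 22 rose by as much as MYH4. Of possible sources of shared reads, MYH13, MYH8, MYH1 and MYH2 had at most 1 count in a control, and the neighbour MYH3 had 366 to 452 there, enough to meet the prediction for reads shared between paralogs, but it stood beside 0 counts of MYH4 in the same libraries, which argues against MYH3 as their source. On the other strand 2 annotated antisense genes, MYHAS and AC005323.2, overlap MYH4, neither is in the table and the strand setting is not stated, so antisense RNA may hold these counts, and no biological explanation was tested.

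For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split was the largest, 1 of 10, in palmitate against control (22 genes, highest other 0), low (10132, 0), medium (10468, 0) and high butyrate against palmitate (14532, 0), high against low (11709, 1) and medium (11291, 0), and low (9019, 0), medium (9518, 0) and high butyrate against control (14217, 0). Medium against low butyrate had 0 genes, the highest other 8, and all 10 splits were as large. Over 100 regroupings each, the real count was the largest for the dose trend (1 as large; 14296 genes, highest other 8391) and genes shared by the doses (1; 10631, highest other 1). This argues against labels unrelated to the libraries. The other regroupings mix libraries that differ at up to 14532 genes and had a median of 0 calls. Their rank therefore does not measure how many of the calls arose by chance. For genes opposed by low (1; 14, highest other 8), medium (1; 15, highest other 1) and high butyrate (4; 13, highest other 13300) the regroupings mix libraries that differ at up to 14532 genes, and their median was 0, so for these few genes they leave chance open. The splits with 13300, 13222 and 13199 opposed genes put the palmitate label on the 3 high-butyrate libraries, and the trend split with 8391 called many genes too, so these point to a structure of the samples.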
